A study of Rattus norvegicus with 4 samples.

How the data were processed

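RNA of primary rat hepatocytes treated with growth hormone (bGH in the labels, the usual short name of bovine growth hormone) was compared with RNA of untreated hepatocytes on 2-channel microarrays, on which both RNAs are hybridised together and each feature gives a ratio. The series holds 4 samples, 2 at 24 h and 2 at 48 h of treatment at 100 ng/ml. Per the labels, treated RNA was in channel 2 on the first 24 h array and the second 48 h array, and in channel 1 on the other two. Both 48 h labels name Cy3 as the dye of the treated RNA although its channel differs between them, so the dyes at 48 h are not settled and the channels were used. Per the labels, cells grew on Matrigel, a basement membrane extract, in a medium (Williams E) to which insulin and vitamin C had been added. A high insulin concentration is named for the 24 h samples only. The labels speak of 4 biological replicates and 8 hybridisations, while each time has 2 columns of values. Whether a column is 1 array or a mean over several is not given in the sources used here, and a column is called an array below. The 24 h labels name different batches of cells, and that of the second 24 h array also the same batch. Whether the arrays of a time came from separate cultures is thus not settled by the labels. The p-values therefore measure only the spread between arrays, which may be technical.

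The values are signed log ratios as deposited by the authors, 1 per feature and array, and are treated here as log2 values. The log base, the numerator channel, the background correction and the normalization are not given in the sources used here. The array medians lay between -0.0034 and 0.0153, so the deposited log ratios were already centred. Ratios reached -6.68, more than a log10 ratio from a 16-bit scanner image can reach, while a natural logarithm is not excluded. Channel intensities were not used here, so neither signal over background nor saturation can be judged. Of the 8937 values, 2528 were written with 3 significant digits. Among values of at least 0.1 in size this happened in 613 rows, and in all 613 an earlier value of the row was smaller than 0.1, so it is a trait of how the table was written.

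Features carry plate-and-well IDs from 65 plates. None of the 6240 IDs matched a symbol, synonym or accession in the rat RefSeq gene table (assembly GRCr8), so no feature is given a gene name. The 24 gene lists fixed before the data were examined, among them growth hormone targets, sex-biased liver genes, lipid metabolism and markers of other liver cell types, could not be tested for the same reason.

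The direction of the ratios followed a rule set before the data were examined. Where the arrays of a time correlate above 0 although the treated RNA lies in opposite channels, the columns are taken as already turned to treated over untreated by the authors. All 6 pairs of columns correlated above 0, so none was turned. The correlations do not show which RNA is the numerator, and they would be the same with all signs turned. The direction is therefore not settled, and the text speaks of positive and negative ratios.

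The 1204 features with a value on all 4 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per time and a spread shared by both times, which gave 2 residual and 3.77 prior degrees of freedom per feature. The contrasts were 24 h against 0, 48 h against 0, 48 h minus 24 h, and the mean over both times against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact sign-flip test cannot go below p = 0.5 with 2 arrays or 0.125 with 4, so single features have no such test. The rule for naming, set before the data were examined, took up to 12 genes of each direction by mean ratio among those that passed with the same sign on every array, and, with no gene symbols, the 2 highest and 2 lowest feature IDs. These were taken from the test over both times. The number of arrays limits the precision: the median standard error was 0.21 at each time and 0.15 over both times.

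The fit was tested on simulated data of 1204 features, with the spread of each feature taken from the real fit and 200 features changed. At 24 h it recovered, in the right direction, 65 of 100 features changed by 1 log2 unit and 88 of 100 changed by 2, with 13 calls among 1004 unchanged features. At 48 h it recovered 64 and 88, with 1 such call. Over both times it recovered 90 and 97, with 11 such calls. For the difference between times, simulated separately with changes at 48 h only, it recovered 40 and 82, with 6 such calls. The true SD of each simulated feature was its residual SD in the real fit. That is an imprecise value on 2 degrees of freedom, which may shift these rates. The simulated noise was normal, independent and of equal spread on all arrays. The real arrays differed in spread, with SDs over the common features from 0.42 to 0.84, so these rates may not hold for them.

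The alternatives were median centring, scaling to equal median absolute deviation, quantile normalization, a channel term, a laxer rule on missing values, array weights, robust moderation, averaging the arrays of a time into 1 value, rules of sign and size, other thresholds, leaving out each array, and turning the signs. A reading of the columns as channel 2 over channel 1 was added after seeing the data. A filter on low signals could not be made from ratios.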

Results

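The data compare RNA levels in primary rat hepatocytes, the main metabolic cells of the liver and a direct target of the pituitary's growth hormone, with and without 24 h or 48 h of growth hormone in culture. Treated and untreated cells were harvested together and compared on the same array, with 2 arrays per time and the channels of the treated RNA exchanged between them. Of 6240 features, 1204 had a value on all 4 arrays, 717 on 3, 645 on 2, 680 on 1 and 2994 on none. The first 24 h array had 1306 values, the second 24 h array 2435, the first 48 h array 2406 and the second 48 h array 2790. The spread of the ratios over the 1204 common features differed between arrays. It was 0.84 (SD over features) on the first and 0.57 on the second 24 h array, and 0.63 on the first and 0.42 on the second 48 h array. The features have no gene names here, so results are given for array features by ID and count. The numerator of the ratios is not given in the sources used here, so a positive ratio is not known to mean a higher level in treated cells. Whether the columns were already turned is not given either. If they were not, the calls below may reflect a channel or dye bias rather than growth hormone, and the ratios alone cannot tell these apart.

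The first question was whether the arrays of treated against untreated cells gave the same picture. Of the 1204 features, 462 (38.4%) had a ratio of the same sign on all 4 arrays, 264 of them positive and 198 negative. Independent signs would give 12.5%, or 150.5 features. The arrays of 24 h correlated with r = 0.67 (Spearman rho 0.55) and those of 48 h with r = 0.45 (rho 0.35), across features, which are not independent replicates. Between times, the first arrays correlated with r = 0.72, the second arrays with r = 0.36, the first 24 h with the second 48 h array with r = 0.21, and the second 24 h with the first 48 h array with r = 0.58. A channel term added to the limma fit passed an adjusted p of 0.05 for 0 features, and 5 had an unadjusted p under 0.05, where 60.2 would come by chance. A term for the first against the second arrays of the times passed for 26 features, and 271 had an unadjusted p under 0.05. Each of these 2 terms was tested against a spread that holds the other contrast, whose mean square was 0.091 for channel and 0.27 for first against second arrays, which lowers the channel count and raises the other. If the columns are instead channel 2 over channel 1 and were never turned, 41 features have the same sign on all 4 arrays and 0 pass the test at 24 h, at 48 h or over both times. The columns were left unturned because they correlate above 0. The excess of same signs and its loss on turning follow from those correlations, so they do not show which reading is right.

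At 24 h of growth hormone, 57 of 1204 features passed the limma test, 13 with positive and 44 with negative ratios. All 57 had the same sign on both arrays, and 55 had a mean ratio at least 1 log2 unit from 0, a change of at least 2 times. The median size among the 57 was 1.52, from 0.97 to 5.51. At an unadjusted p under 0.05 there were 275 features, 95 positive and 180 negative, against 60.2 by chance. RNABT12 had a ratio of 2.30 ± 0.19 (SD, n = 2 arrays) and RNABK02 one of 3.03 ± 0.71, while RGIAP58 was at -1.66 ± 0.017 and RGIAI10 at -2.01 ± 0.36. These 4 passed at 24 h with limma adjusted p values of 0.016, 0.021, 0.016 and 0.016. They were chosen for extreme means and a pass over both times, so a pass at 24 h or 48 h was favoured beforehand. After quantile normalization 39 features passed, 14 positive and 25 negative, which lowers the share of negative calls, and RGIAP58 (-1.40, limma adjusted p = 0.11) and RGIAI10 (-1.62, 0.063) did not. With arrays scaled to equal median absolute deviation, RNABT12, RGIAP58 and RGIAI10 did not pass at 24 h, with ratios of 2.01, -1.52 and -1.78 (limma adjusted p = 0.089, 0.13 and 0.065). The count was 31 with a channel term, 32 among features with a value on at least 1 array of each time, and 34 with array weights. Without the first 24 h array 0 features passed at 24 h, and the 4 named features then had ratios of 2.17, 2.52, -1.64 and -1.75, with limma adjusted p values of 0.063.

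At 48 h, 13 features passed, 7 positive and 6 negative, all with the same sign on both arrays and all at least 1 log2 unit from 0. Their median size was 1.69, from 1.30 to 3.47. At an unadjusted p under 0.05 there were 150 features, 64 positive and 86 negative. RNABT12 was at 3.0 ± 0.49 (SD, n = 2 arrays), RGIAP58 at -3.47 ± 0.14 and RGIAI10 at -3.04 ± 0.16, with limma adjusted p values of 0.0068, 0.0019 and 0.0051. RNABK02 was at 1.75 ± 0.85 and did not pass (limma adjusted p = 0.12), but passed after scaling to equal median absolute deviation (0.015), after quantile normalization (0.043) and with the first or the second 24 h array left out (0.042 each). Its limma adjusted p was 0.18 with a channel term and 0.19 with the laxer rule on missing values, and without the first 48 h array its ratio was 1.15 (limma adjusted p = 0.97). The count differed under other normalizations: 40 features passed after scaling to equal median absolute deviation (19 positive, 21 negative) and 30 after quantile normalization (11 positive, 19 negative). It was 4 with a channel term and 3 among features with a value on at least 1 array of each time. Without the second 48 h array 0 features passed, and RNABT12, RGIAP58 and RGIAI10 had ratios of 2.65, -3.37 and -2.93 with limma adjusted p values of 0.059, 0.053 and 0.059. Without the first 48 h array 3 passed, and with the first or the second 24 h array left out 24 passed each time.

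**Figure D1:**
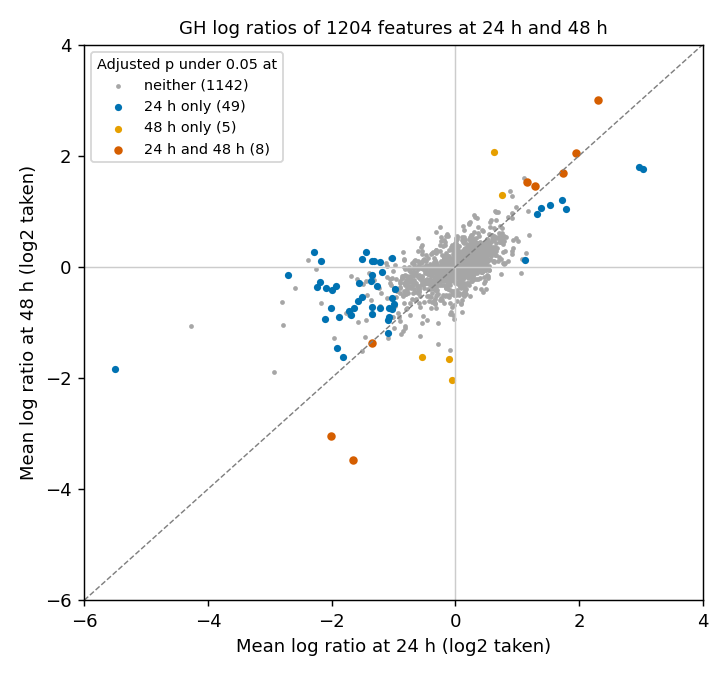
Mean log ratio (log2 taken) of the 2 arrays at 24 h (x axis) against that at 48 h (y axis) for each of the 1204 features, coloured by the time at which limma's adjusted p was under 0.05; the dashed line marks equal ratios. Of the 57 features called at 24 h, 44 lie at negative ratios, and 8 of the 57 were also called at 48 h.

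The ratios of treated against untreated cells at the 2 times were related across features. The means of 24 h and 48 h correlated with r = 0.64 (95% bootstrap interval over features 0.60 to 0.69) and Spearman rho 0.63. Without the 2 features farthest from the median at 24 h, r was 0.64. Without the first 48 h array it was 0.30, and from single arrays it ranged from 0.21 to 0.72. Among the features called, 8 passed at both times, 5 positive and 3 negative, where independent lists would share 0.615. The times share 1 estimate of the spread per feature, which adds to this overlap. Of the 57 features called at 24 h, 49 had a mean of the same sign at 48 h and 46 the same sign on all 4 arrays. The 13 features called at 48 h all had the same sign at 24 h, and 12 of them the same sign on all 4 arrays. The features called at 24 h had a median ratio of 1.52 at 24 h and 0.74 at 48 h in the direction of the call, but they were chosen on their 24 h values, which favours a smaller value elsewhere. Those called at 48 h, chosen on their 48 h values, had a median of 1.69 at 48 h and 1.28 at 24 h.

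The difference between the times was tested directly. With limma, 0 of 1204 features differed between 48 h and 24 h at an adjusted p under 0.05, and the smallest adjusted p was 0.16. At an unadjusted p under 0.05 there were 79 features, 54 with a higher and 25 with a lower ratio at 48 h, against 60.2 by chance. The count was also 0 with array weights and with robust moderation, and 4 without the second 24 h array. At an unadjusted p under 0.01 and at least 1.5 times, 18 features had a higher and 3 a lower ratio at 48 h. The named features were chosen by their means over both times, so they do not represent the difference between times. RGIAP58 had the lower ratio at 48 h, by a difference of -1.81 ± 0.25 (SE), which did not pass (limma adjusted p = 0.16). The differences for RNABT12 (0.70 ± 0.33, SE), RNABK02 (-1.27 ± 0.52) and RGIAI10 (-1.03 ± 0.29) did not pass either.

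Over both times together, 98 features passed, 32 positive and 66 negative. Of these, 91 had the same sign on all 4 arrays and 51 had a mean ratio at least 1 log2 unit from 0. The median size was 1.02, from 0.58 to 3.67. Among the features that passed with the same sign on every array, the highest mean ratios were those of RNABT12, at 2.65 ± 0.51 (SD, n = 4 arrays), or 6.28 times if the base is 2, and of RNABK02, at 2.39 ± 0.98, or 5.24 times. The lowest mean ratios among them were those of RGIAP58, at -2.56 ± 1.05, or 5.91 times, and of RGIAI10, at -2.52 ± 0.64, or 5.74 times. Their limma adjusted p values were 0.0019, 0.010, 0.0015 and 0.0019. These rest on the spread within times, while the SD over 4 arrays also holds the difference between times. With a channel term 57 features passed, 16 positive and 41 negative. With the arrays of a time averaged into 1 value, as suits a technical exchange of the channels, 74 features passed, 57 of them among the 98. RNABT12, RNABK02, RGIAP58 and RGIAI10 then had limma adjusted p values of 0.0037, 0.0083, 0.014 and 0.0053. Without the first 48 h array 10 features passed, 6 positive and 4 negative, so the larger share of negative ratios was not kept. Without the first 24 h array 61 passed, 18 positive and 43 negative.

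**Figure D2:**
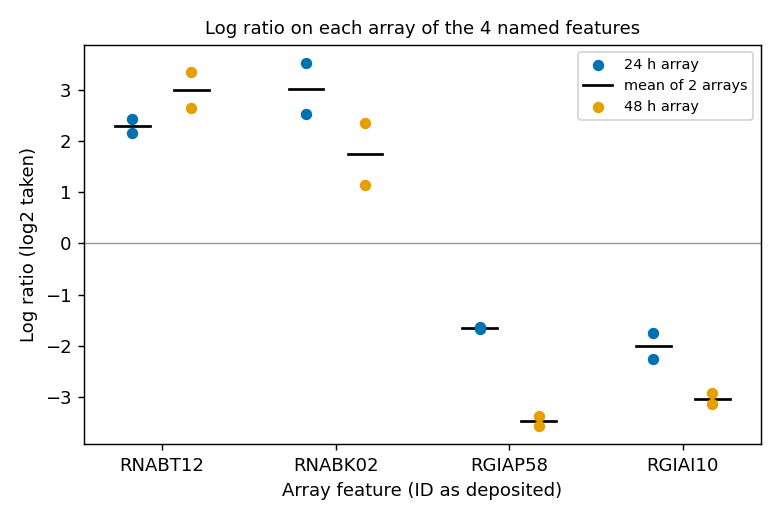
Log ratio (log2 taken, y axis) of the 4 named array features (x axis) on each of the 2 arrays at 24 h and at 48 h, with black lines at the mean of each time. RNABT12 and RNABK02 lie between 1.15 and 3.53 on every array, and RGIAP58 and RGIAI10 between -3.57 and -1.64.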

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

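Both tests in this part were chosen after the counts were seen. They treat features as independent, although features of a plate may share shifts, so their p-values may be too small. Features with values on both 48 h arrays and on neither 24 h array took no part in the comparisons above. Of 333 such features, 15 had the same sign on both arrays and a mean at least 1 log2 unit from 0, which is above the 3 that a count of 0 allows, but that limit is not the number chance gives. Shuffling the values of one array over the features gave 8.39 such features on average and 19 at the highest (permutation test, one-sided, p = 0.0030). All 15 ratios were negative and 0 were positive. Among the 1204 features measured on all 4 arrays, the same rule at 48 h gave 43 features, 19 positive and 24 negative (Fisher's exact test of the direction, two-sided, p = 0.0011). Both 48 h arrays correlated with r = 0.29 over the 333 features, and 57.4% had the same sign on both, where chance gives 50%.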

How the results depend on the processing

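The fit with all 4 arrays gave 57 calls at 24 h, 13 at 48 h, 0 for the difference and 98 over both times. At 24 h the count moved to 31 with a channel term, 32 with a value on at least 1 array of each time, 34 with array weights, 102 and 271 by the same sign and a mean of at least 2 and 1.5 times, 130 at an adjusted p under 0.1 and 127 at an unadjusted p under 0.01 with 1.5 times. At 48 h it moved to 40 with equal median absolute deviation, 30 after quantile normalization, 4 with the channel term, 3 with the laxer rule on missing values, 43 and 132 by sign and size, 27 at an adjusted p under 0.1 and 57 at the unadjusted threshold. For the difference between times, 43 and 141 features had no overlap of the arrays and a difference of at least 2 and 1.5 times, and 21 passed the unadjusted threshold; chance alone leaves 33.3% of features without overlap, before any rule of size. Over both times the count moved to 57 with the channel term, 56 by the same sign and at least 2 times, and 190 at an adjusted p under 0.1. The channel term takes up 1 of the 2 residual degrees of freedom. It also leaves a spread that holds only the contrast of first against second arrays. The mean square of that contrast was 0.27, against 0.091 for channel. Which of these lowered the counts was not tested, nor was the cause of the other moves. The correlation between times was 0.60 with equal median absolute deviation and 0.50 with the laxer rule; from single arrays it was 0.72, 0.21, 0.58 and 0.36. Leaving out 1 array in turn, with the lone array taken to vary like those of the other time, gave 0 to 66 calls at 24 h, 0 to 24 at 48 h, 0 to 4 for the difference, 10 to 145 over both times and correlations of 0.30 to 0.72.

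Turning all signs, which the unstated numerator leaves open, keeps the totals and exchanges the directions: 44 positive and 13 negative calls at 24 h, 6 and 7 at 48 h, and 66 and 32 over both times. It turns the ratios of RNABT12, RNABK02, RGIAP58 and RGIAI10 to -2.30, -3.03, 1.66 and 2.01 at 24 h, to -3.0, -1.75, 3.47 and 3.04 at 48 h and to -2.65, -2.39, 2.56 and 2.52 over both times. Reading the columns as channel 2 over channel 1, chosen after seeing the data, gave 0 calls at 24 h, at 48 h and over both times, 41 features of the same sign on all arrays and a correlation between times of -0.50. Columns that correlate above 0 as deposited lead to such a loss once some of them are turned. This reading turned RNABK02 to -0.60 at 48 h and -0.049 over both times. The other named features kept their sign, but over both times RNABT12 moved to 0.24, RGIAP58 to -0.057 and RGIAI10 to -0.18. The naming rule required the same sign on every array, so the direction of the 4 named features could not turn when an array was left out, and it says nothing about stability. The rule also required a pass over both times and took the most extreme means. Passing over both times again in refits of the same arrays therefore says little about stability. Under the 12 other settings that refit the ratios, 12 of their 136 values lost and 4 gained their call, and over both times they passed in each, with limma adjusted p from 0.0010 to 0.037. A filter on low signals was not run, as it needs intensities. No gene list result exists to vary.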

Other observations

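The tests of the turning of the ratios and the count over the ways of turning them were chosen after the result was seen; those of amplitude and of neighbouring wells were set down before their result, but after the pattern was noticed.

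The share of negative calls differed between the 2 large families of feature IDs. Among 708 features whose IDs start with RGI, 11 passed over both times with positive and 48 with negative ratios, and among 489 that start with RNA, 20 and 17 (Fisher's exact test of the direction, two-sided, p = 0.00062, chosen after the counts were seen). The median ratios of the families over all their features were -0.015 and 0.055. Fisher's exact test treats features as independent, but each plate lies within a single family of IDs. Mean ratios of neighbouring wells of a plate correlated with rho 0.22, and with rho 0.076 once each plate's median was subtracted. The p-value therefore cannot be taken at face value. A difference between families was not separated from differences between single plates.

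The ratios correlated above 0 between arrays with the treated RNA in opposite channels. One candidate explanation is growth hormone in ratios already turned by the authors; the other is a channel or dye bias in ratios that were never turned. A fixed bias would not depend on time, but the covariance of opposite-channel arrays within a time exceeded that between times by -0.014 (95% bootstrap interval -0.033 to 0.0057), so this test did not separate them. Covariance was lower for arrays of the same than of opposite channels, by -0.083 (-0.0998 to -0.068), which neither reading predicts for an effect that is the same at both times. Both same-channel pairs join arrays of different times, and covariance also depends on the spread of each array. This value therefore does not separate the readings. The 2 readings cannot be told apart from ratios alone. Of the 8 ways of turning the columns, 1, the deposited one, gave as many as 98 calls over both times and the highest of the others gave 1, but 8 ways are too few for a share under 0.05. The deposited way was also favoured beforehand, since all pairs of columns correlate above 0 in it.

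The first arrays of the 2 times resembled each other (r = 0.72) more than the first 48 h array resembled the other 48 h array (difference in r 0.27, 95% bootstrap interval 0.18 to 0.36); at 24 h that difference was 0.047 (-0.0038 to 0.10). A limma term for first against second arrays, which follows neither time nor channel, passed for 26 features. A difference in amplitude between the arrays is one candidate explanation of this term. Scaling an array by a constant leaves r unchanged, so equal scaling cannot address the differences in r. With equal median absolute deviation the term passed for 6 features, and its mean square over that of the larger of the time and channel terms went from 1.11 (0.95 to 1.30) to 0.88 (0.74 to 1.03). Both intervals include 1, so the part of amplitude cannot be told apart from other structure. The correlation of this contrast with the mean ratio over features was 0.57 as deposited and 0.060 with equal scaling. Equal scaling itself lowers this value, so it does not measure the part of amplitude either. No biological explanation was tested, since the labels give no group that joins these arrays.

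Features in neighbouring wells of a plate had similar mean ratios: rho was 0.22 over 357 neighbouring pairs (95% bootstrap interval 0.12 to 0.32). Shifts of whole plates may account for most of this, since rho fell to 0.076 (-0.028 to 0.18) once each plate's median was subtracted; shuffling wells within plates gave a two-sided permutation p of 0.044 for what was left. In the difference between channel orientations, meant as a test of a channel bias by position on the array, rho was lower than in the mean by -0.26 (-0.41 to -0.11). Neighbouring wells of a plate need not lie side by side on the array, and positions on the array were not used. The test therefore cannot decide on such a bias, and whether the ratios were turned is also open. Plates may also differ in the genes they hold, which could not be tested without gene names.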
